A study of Mus musculus with 19 samples.

How the data were processed

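RNA was sequenced from mononuclear cells of hindlimb muscle of C57BL/6J mice, which per the labels' protocols received 2.5 mg tamoxifen daily for 5 days at 8 weeks of age, followed by a washout of 10 days. Cells were sorted, RNA was extracted and stranded poly(A) libraries were made, per the labels. Whole is titled a suspension but also called whole muscle, and the labels do not settle which was sequenced. Groups and replicate numbers come from the sample titles. The labels do not say that replicates came from separate animals, so p values measure only the spread between these samples, which may be technical.

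The deposited values are FPKM per gene, and per the submitters' processing notes bcl2fastq, TopHat2, Bowtie2, Cufflinks and the build mm10 were used. Their versions and roles and the annotation are not given in the sources used here. Cells that could not be estimated hold status words in the deposited table, LOWDATA in 312 per column, FAIL in 16 and HIDATA in 1 over all columns. Of 23846 genes, 311 hold only such words and 14 hold some, and both kinds were left out, which left 23521. The lowest listed value was 0.001. A further 4 columns matched no sample and were not used here. Symbols listed more than once, 252 of them, were tested as separate entries and not named. Starts were shifted to count from 1.

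FPKM are not counts, so no count model was used. Values were taken as log2(FPKM + 1), a scale that understates the change of low genes. Genes with at least 1 FPKM in at least 3 of 19 libraries, 14043 in all, were tested with limma (empirical Bayes with a variance trend, two-sided, 14 residual degrees of freedom) in 1 fit of all 5 groups. In each of 6 comparisons p values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

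A total of 23 gene lists was tested with camera (two-sided, preset correlation 0.01, adjusted over the lists of a comparison), each on its tested members. The correlation was also estimated for each list. The lists were the gate genes, markers of mesenchymal progenitors, satellite cells, blood and lymphatic endothelium, macrophages and monocytes, lymphocytes, neutrophils, pericytes and smooth muscle, tenocytes and Schwann cells, and genes of erythroid cells, myofibres and myocytes, adipocytes, fibrillar collagen and interstitial matrix, basement membrane, complement, growth factors, the Notch pathway, MHC class II, chemokines, the immediate early and stress response and the cell cycle. Some genes stand in more than 1 list. Ly6g and Hbb-bt were not found, Myh4 held status words, and Beta-s is the table's symbol for Hbb-bs. Lists, tests, the rule for naming genes and the alternatives, except those given below as added, were fixed before the data were examined. Named were Pecam1, Ptprc, Ly6a, Pdgfra, Hic1 and Pax7 in every comparison. To these came the 6 largest log2 differences in each direction for LinPos against LinNeg and for LinNegSca1Pos against LinNegSca1Neg, and the 3 largest in the other comparisons. They were taken among called genes with a mean of at least 10 FPKM in the higher group and no overlap. Of each list described up to 4 members with the largest difference were named, and members called against most of their list. Some genes that this rule takes are not reported here.

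Alternatives were pseudocounts of 0.1 and 5, no filter or 5 FPKM in 3 libraries, median-of-ratios scaling, quantile normalization, a fit of the compared groups only, sample weights, no variance trend, the replicate number as a block and leaving out each replicate in turn. Lists were also tested with fry (limma) and the parents with log2-scale means and genes differing at least 4-fold. Added after seeing the data were a term for set B, set A or set B alone, the block in a fit of the paired groups only, and for the lists the scaling, set, block and leave-one-out fits. The replicate numbers paired LinPos with LinNeg and LinNegSca1Neg with LinNeg. Deviations of same-numbered libraries from their group means correlated across genes at 0.44 to 0.70 and 0.55 to 0.78, and 4 of 4 LinPos and 2 of 4 LinNegSca1Neg libraries correlated best with their own number. The pairing comes from the data, since the labels do not say what a number marks, and sets A and B alone could give such correlations. Differences between the libraries of a set correlated across genes at 0.31 in set A and 0.17 in set B for LinPos and LinNeg, and at 0.44 and -0.05 for LinNegSca1Neg and LinNeg, where set B thus showed no pairing.

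Spearman's rho between replicates, across genes, was 0.973 to 0.986 in Whole, 0.919 to 0.983 in LinPos, 0.924 to 0.976 in LinNeg, 0.923 to 0.978 in LinNegSca1Neg and 0.952 to 0.969 in LinNegSca1Pos, and no columns were identical. Depth was not stated and was estimated only relatively, from low values of 1190 genes. The step that 1 fragment is worth was 1.0 to 4.88 times that of Whole replicate 1, the largest in LinNegSca1Pos replicate 3, whose low values are the least precise. The fit was tested on simulated data with 200 of 14043 genes changed. Over the 6 comparisons it recovered 53% to 72% of 2-fold and 92% to 96% of 4-fold changes, with 3.7% to 7.69% of calls false. The simulation changed no genes of low mean level, drew each library independently and held no gap between sets A and B. Far more genes were called in the real data, so these rates may not hold there. Fragments from sequence that genes share cannot be told apart. Values are therefore uncertain for the named genes Beta-s, C4b, Hspa1a, Hspa1b, Igf2, Ly6a, Lyz2, Myh1, Myh2, Myl1, Ndufs5, Rbpj and Snora41, which share at least 20% of their 31-base words with another gene of GENCODE vM21.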

Results

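Poly(A) RNA of cells from the hindlimb muscle of C57BL/6J mice was sequenced in 19 libraries of 5 groups, which followed a nested sort. Whole held 4 libraries, titled a suspension of mononuclear cells in the labels but whole muscle in the deposited columns. Which was sequenced is open. LinPos held 4 libraries of the lineage-positive fraction, described in the labels as endothelial and blood-derived cells. LinNeg held 4 libraries of the lineage-negative remainder. LinNeg was divided by the surface protein Sca1, encoded by Ly6a, into LinNegSca1Pos, 3 libraries of what the labels call mesenchymal progenitors, and LinNegSca1Neg, 4 libraries. Levels are given in FPKM, fragments per kilobase of transcript scaled to the mapped fragments of a library, as mean ± SD with n = 4 libraries, or n = 3 for LinNegSca1Pos. In each comparison the first-named group stands first, and a gene called higher or lower had a limma adjusted p under 0.05 over all tested genes. Where a single count of list members is given, it was the same adjusted over the list alone. Genes at 1 FPKM or more numbered from 10737 in Whole replicate 1 to 12517 in LinNegSca1Neg replicate 2. Myofibre and myocyte genes, which encode the contractile apparatus and its energy supply, made up 18.5% ± 1.32 of the summed FPKM in Whole, 2.70% ± 2.07 in LinNegSca1Neg, 0.973% ± 0.872 in LinNeg, 0.034% ± 0.027 in LinNegSca1Pos and 0.024% ± 0.01 in LinPos. Immediate early and stress genes took 0.024% ± 0.001 in Whole and 1.38% ± 0.086, 1.90% ± 0.147, 1.95% ± 0.247 and 1.35% ± 0.220 in LinPos, LinNeg, LinNegSca1Neg and LinNegSca1Pos. The first principal component of all libraries held 40.5% of the variance and set Whole apart, and the second, with 31.3%, set LinPos apart from the other sorted fractions. Within groups, replicates 1 and 2 of LinPos, LinNeg and LinNegSca1Neg stood apart from replicates 3 and 4 on a first component with 45.9% of the within-group variance. The labels name no batch. Results are therefore also given from set A, replicates 1 and 2 of these 3 groups, and from set B, replicates 3 and 4, each with all Whole and LinNegSca1Pos libraries.

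**Figure D1:**
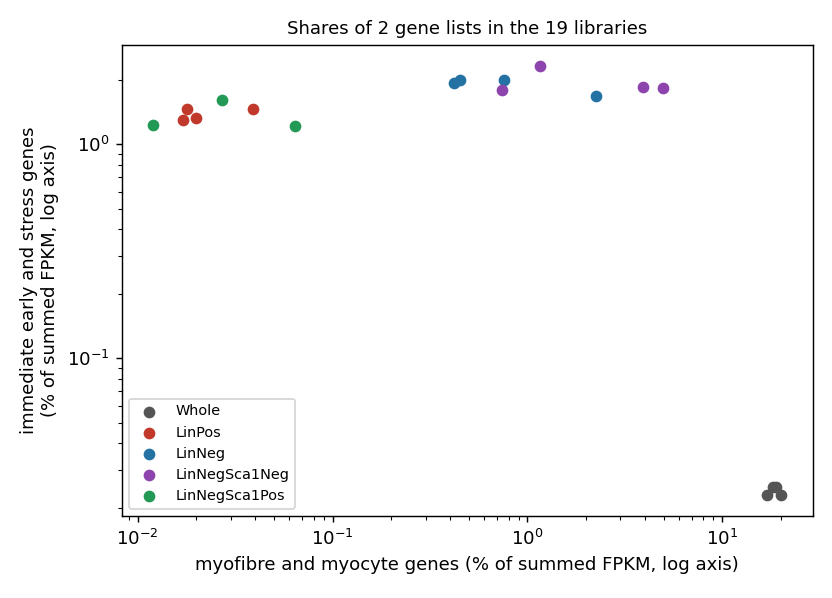
Each point is 1 of the 19 libraries, coloured by group. The x axis gives the myofibre and myocyte genes and the y axis the immediate early and stress genes, both as percent of summed FPKM on log axes. The 4 Whole libraries lie between 16.9% and 20.04% on the x axis and at or below 0.025% on the y axis.

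**Figure D2:**
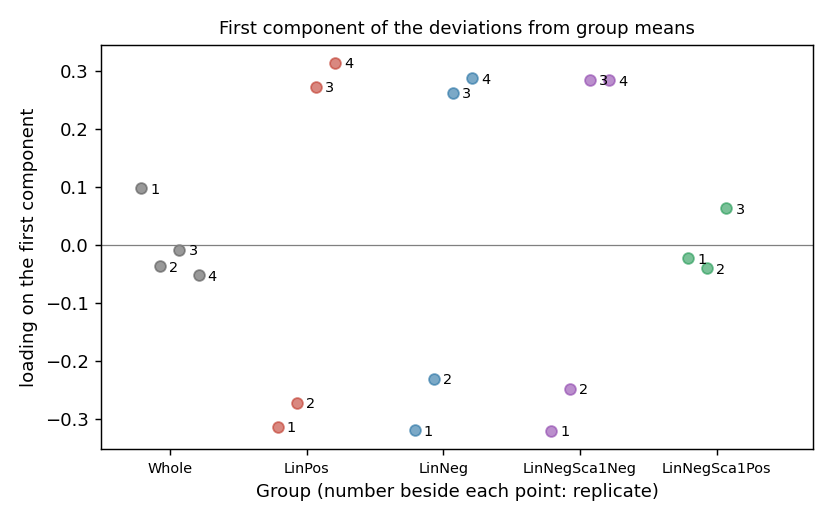
Loading of each library on the first component of the deviations from group means (y axis, no unit), by group (x axis), with the replicate number beside each point. Replicates 1 and 2 of LinPos, LinNeg and LinNegSca1Neg lie at or below -0.231, and replicates 3 and 4 at or above 0.263.

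The comparison of LinPos with LinNeg asked what the lineage gate separated. Pecam1 (chromosome 11, 106654218 to 106715281, mm10), which encodes the endothelial adhesion protein CD31, was at 303 ± 96.0 against 5.24 ± 1.39 FPKM, a log2 difference of 5.57 ± 0.34 (SE, limma adjusted p = 1.2e-10). Ptprc (chromosome 1, 138062859 to 138175305), which encodes the leukocyte protein CD45, was at 131 ± 40.3 against 1.38 ± 1.19 FPKM, a log2 difference of 5.86 ± 0.30 (limma adjusted p = 8.6e-12). Ly6a (chromosome 15, 74994877 to 74998031) was abundant in both groups, at 604 ± 139 against 1243 ± 199 FPKM, and lower in LinPos with a log2 difference of -1.06 ± 0.23 (limma adjusted p = 6.1e-04). Pdgfra (chromosome 5, 75152291 to 75198204), a PDGF receptor that marks mesenchymal progenitors, was at 4.88 ± 1.41 against 105 ± 23.7 FPKM (log2 difference -4.18 ± 0.19, limma adjusted p = 1.8e-12). The transcription factor gene Hic1 (chromosome 11, 75164565 to 75170255) was lower in LinPos, at 1.52 ± 0.368 against 5.59 ± 1.39 FPKM (limma adjusted p = 1.0e-05). The satellite cell factor Pax7 (chromosome 4, 139738081 to 139832968) was lower, too, at 0.185 ± 0.174 against 7.13 ± 5.17 FPKM (limma adjusted p = 2.8e-05). Of 3 gate genes 2 were higher and 1 lower (median log2 difference 5.57, camera adjusted p = 0.114).

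**Figure D3:**
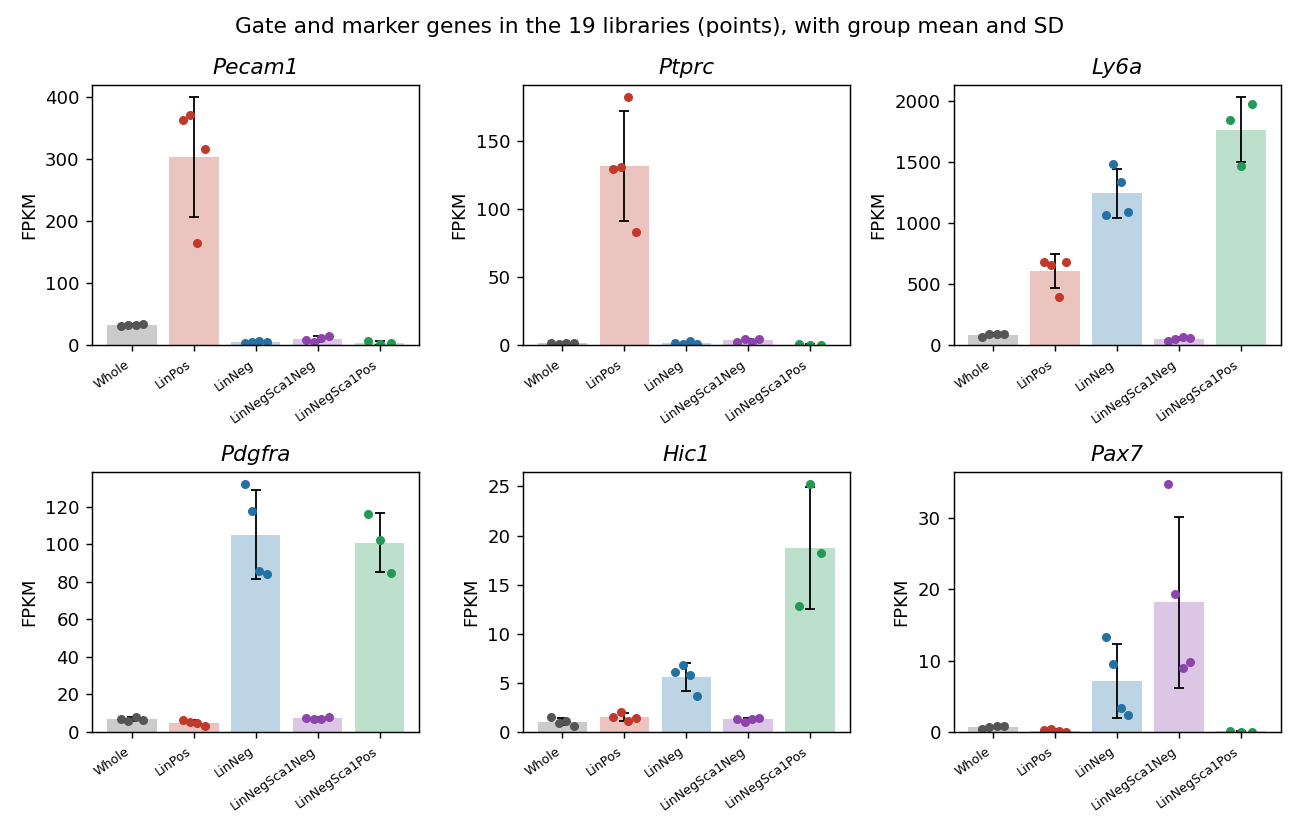
FPKM (y axis, linear) of the gate genes Pecam1, Ptprc and Ly6a and of Pdgfra, Hic1 and Pax7 in the 5 groups (x axis). Bars are group means, error bars SD and points the single libraries. Pecam1 and Ptprc are highest in LinPos, Ly6a and Hic1 in LinNegSca1Pos and Pax7 in LinNegSca1Neg.

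Markers of endothelium and of blood-derived cells were higher in LinPos. The largest increases without overlap between the libraries were Retnla, a secreted protein of macrophages, at 8068 ± 5805 against 11 ± 10.1 FPKM (log2 difference 9.46, limma adjusted p = 5.8e-08), H2-Aa at 2405 ± 706 against 4.88 ± 3.58 FPKM (log2 difference 8.79, adjusted p = 4.6e-10) and Cd74, the invariant chain, at 2943 ± 442 against 8.97 ± 6.09 FPKM (log2 difference 8.37, adjusted p = 1.9e-09). They were followed by H2-Ab1 at 1972 ± 1385 against 5.53 ± 5.47 FPKM (log2 difference 8.35, limma adjusted p = 5.9e-09), C1qc at 390.1 ± 290.3 against 0.216 ± 0.217 FPKM (log2 difference 8.10, adjusted p = 5.1e-10) and Pf4, a chemokine of platelets, at 946 ± 1116 against 1.15 ± 0.621 FPKM (log2 difference 8.10, adjusted p = 4.2e-09). Of 12 blood endothelial markers 11 were higher (median log2 difference 5.00, camera adjusted p = 1.0e-07, adjusted p = 0.144 with an estimated correlation). Kdr, a VEGF receptor, was at 137 ± 78.6 against 1.44 ± 0.348 and Emcn, endomucin of vessel walls, at 189 ± 85.2 against 2.99 ± 1.10 FPKM. All 12 macrophage and monocyte markers were higher (median log2 difference 6.74, camera adjusted p = 4.7e-11, adjusted p = 0.0611 with an estimated correlation). C1qb, a chain of complement C1q, was at 400.2 ± 92.7 against 0.466 ± 0.235 and Ctss, a lysosomal protease, at 639 ± 205 against 1.96 ± 2.02 FPKM. All 7 MHC class II genes were higher (median log2 difference 7.88, camera adjusted p = 2.1e-06, adjusted p = 0.0788 with an estimated correlation). H2-Eb1 was at 772 ± 133 against 2.51 ± 1.76 FPKM. All 8 neutrophil markers were higher (median log2 difference 6.30, camera adjusted p = 1.9e-04, adjusted p = 0.198 with an estimated correlation). S100a8, a protein of neutrophils, was at 38348 FPKM in LinPos replicate 3, from 2903 to 5591 in the other 3 libraries, and at 206 ± 336 in LinNeg (limma adjusted p = 2.0e-04). All 11 lymphocyte markers were higher (median log2 difference 2.46, camera adjusted p = 1.7e-05, adjusted p = 0.197 with an estimated correlation). Cd2, an adhesion protein of T and NK cells, was at 25.1 ± 12.4 against 0.521 ± 0.620 and Nkg7, a granule protein of cytotoxic cells, at 13.6 ± 6.98 against 0.483 ± 0.534 FPKM. All 12 cell cycle genes were higher (median log2 difference 1.19, camera adjusted p = 0.00329, adjusted p = 0.378 with an estimated correlation). Mki67, a proliferation marker, was at 13.5 ± 7.89 against 3.23 ± 2.49 and Birc5, survivin, at 17.4 ± 14.4 against 4.81 ± 4.82 FPKM.

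Markers of stromal, muscle and nerve sheath cells were lower in LinPos. Among the largest decreases without overlap were Efemp1, a matrix glycoprotein, at 12 ± 4.73 against 473 ± 156 FPKM (log2 difference -5.20, limma adjusted p = 1.8e-11), Tnnc2, a fast troponin, at 19.5 ± 16.5 against 952 ± 1107 FPKM (log2 difference -5.15, adjusted p = 2.0e-05) and Tnnt3, a fast troponin, at 23.7 ± 15.5 against 1064 ± 1049 FPKM (log2 difference -5.14, adjusted p = 2.5e-06). Next came Mfap5, a microfibril protein, at 16 ± 2.54 against 592 ± 99.7 FPKM (log2 difference -5.12, limma adjusted p = 1.7e-13) and Acta1, skeletal actin, at 24.1 ± 17.7 against 1007 ± 1141 FPKM (log2 difference -5.00, adjusted p = 6.2e-05). All 12 mesenchymal progenitor markers were lower (median log2 difference -4.46, camera adjusted p = 7.8e-10, adjusted p = 0.0321 with an estimated correlation). Clec3b, tetranectin, was at 15.3 ± 8.88 against 430.3 ± 209.8 FPKM. All 16 fibrillar collagen and interstitial matrix genes were lower (median log2 difference -4.43, camera adjusted p = 4.7e-11, adjusted p = 0.0736 with an estimated correlation). Col3a1 was at 130.4 ± 23.1 against 3429 ± 825 and Col6a2 at 15.4 ± 3.19 against 402 ± 109 FPKM. Of 13 basement membrane genes 10 were lower and 1 higher (median log2 difference -1.75, camera adjusted p = 3.0e-04, adjusted p = 0.198 with an estimated correlation). Lama2, a laminin chain of muscle, was at 4.12 ± 1.52 against 87.5 ± 37.1 and Nid1, nidogen, at 42.9 ± 9.18 against 399 ± 61.1 FPKM. Lama5 at 8.49 ± 3.96 against 4.27 ± 0.856 FPKM was higher. Lama5 was not called without LinNeg replicate 3 or LinPos replicates 1 or 2 or in set B (limma adjusted p from 0.0572 to 0.233). All 12 satellite cell markers were lower (median log2 difference -2.58, camera adjusted p = 4.0e-08, adjusted p = 0.0736 with an estimated correlation). Chodl was at 3.05 ± 0.505 against 89.7 ± 7.25 and Chrdl2 at 0.655 ± 0.369 against 23.7 ± 5.70 FPKM. All 10 tenocyte markers were lower (median log2 difference -3.77, camera adjusted p = 3.6e-06, adjusted p = 0.144 with an estimated correlation). Thbs4, a thrombospondin, was at 15.1 ± 3.34 against 385 ± 194 and Tnmd, tenomodulin, at 7.06 ± 1.70 against 185 ± 101 FPKM. Of 9 Schwann cell markers 8 were lower (median log2 difference -2.62, camera adjusted p = 1.0e-04, adjusted p = 0.144 with an estimated correlation). Kcna1, a potassium channel, was at 0.938 ± 0.239 against 19.1 ± 1.69 FPKM. Of 12 pericyte and smooth muscle markers 9 were lower (median log2 difference -1.45, camera adjusted p = 0.00267, adjusted p = 0.198 with an estimated correlation). Acta2, smooth muscle actin, was at 148 ± 123 against 626 ± 215 and Cnn1, calponin, at 3.13 ± 4.05 against 14.5 ± 3.44 FPKM. Of 11 myofibre and myocyte genes 10 were lower (median log2 difference -4.69, camera adjusted p = 4.3e-05, adjusted p = 0.198 with an estimated correlation). In LinNeg the myofibre share of the summed FPKM was 2.26% in replicate 3 and from 0.422% to 0.76% in the other 3 libraries.

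Lists of secreted and signalling genes went both ways. Of 18 growth factor genes 13 were lower and 2 higher (median log2 difference -1.69, camera adjusted p = 7.6e-04, adjusted p = 0.0324 with an estimated correlation). Fst, follistatin, was at 3.51 ± 1.5 against 89.7 ± 15.2 and Gdf10 at 10.1 ± 4.61 against 127 ± 28.4 FPKM. Tgfb1 at 33.6 ± 8.08 against 6.43 ± 1.96 and Pdgfb at 43.0 ± 14.6 against 1.67 ± 0.178 FPKM were higher. Of 18 chemokine genes 10 were higher and 4 lower (median log2 difference 0.93, camera adjusted p = 0.14). Ccl6 was at 423 ± 62.0 against 1.68 ± 0.185 and Ccl9 at 205 ± 72.9 against 0.673 ± 0.194 FPKM. Ccl11, eotaxin, at 14.9 ± 5.60 against 411 ± 61.0, Cxcl1, a chemokine that attracts neutrophils, at 38.6 ± 21.1 against 378 ± 51.8, Cxcl13 at 2.87 ± 1.31 against 50.05 ± 12.9 and Cxcl14 at 11 ± 3.16 against 223 ± 34.1 FPKM were lower. Of 11 complement genes 6 were lower and 3 higher (median log2 difference -1.18, mean 0.38, camera adjusted p = 0.258). Serping1, the C1 inhibitor, was at 66.5 ± 14 against 1398 ± 278 FPKM. C1qa at 187 ± 63.0 against 0.0792 ± 0.0334 FPKM was higher. Of 13 Notch pathway genes 7 were higher and 4 lower (median log2 difference 0.87, camera adjusted p = 0.276). Dll4, an endothelial Notch ligand, was at 32.6 ± 11.5 against 0.377 ± 0.1003 FPKM. Hey2 at 1.76 ± 1.56 against 8.07 ± 3.26, Jag1 at 14.9 ± 1.96 against 30.5 ± 2.71, Notch3 at 4.20 ± 0.955 against 16 ± 5.90 and Heyl at 2.14 ± 0.618 against 16.4 ± 4.77 FPKM were lower. Of 5 lymphatic endothelial markers 3 were higher and 2 lower (median log2 difference 1.84, camera adjusted p = 0.212). Lyve1, a hyaluronan receptor, was at 107 ± 66.8 against 0.428 ± 0.187 FPKM. Prox1 at 0.240 ± 0.0735 against 1.76 ± 0.817 and Reln, reelin, at 0.820 ± 0.299 against 11.2 ± 2.48 FPKM were lower. Of 17 immediate early and stress genes 5 were lower and 1 higher (median log2 difference -0.24, camera adjusted p = 0.212). Egr1, an immediate early factor, was at 271 ± 68.3 against 1043 ± 145 FPKM. Dusp1 at 761 ± 108 against 442 ± 39.0 FPKM was higher. Dusp1 was not called in set A (limma adjusted p = 0.0927). Of 7 adipocyte genes 1 was higher and 1 lower (median log2 difference -0.03, mean 0.14, camera adjusted p = 0.797 towards higher relative to other genes). Pparg, a nuclear receptor of fat cells, was at 28.0 ± 6.49 against 5.53 ± 0.514 and Plin1, a lipid droplet protein, at 0.0311 ± 0.0601 against 0.822 ± 0.424 FPKM. Plin1 was not called without LinNeg replicate 1 (limma adjusted p = 0.0564), without LinNeg replicate 2 (0.0651) or in set B (0.411). Of 4 erythroid genes 1 was higher, or 0 adjusted over the list alone (median log2 difference 1.05, camera adjusted p = 0.479). Beta-s was at 5598 ± 5964 against 2352 ± 2972 (limma adjusted p = 0.141) and Alas2, an enzyme of haem synthesis, at 24.5 ± 15.4 against 7.21 ± 8.12 FPKM. Beta-s was called without LinNeg replicate 3 (limma adjusted p = 0.0316), in set A (2.9e-04) or with a term for set B (0.0246). Alas2 was not called without LinNeg replicates 1, 2 or 4 or LinPos replicates 1 or 2, in set B or with the replicate number as a block in a fit of these groups alone (limma adjusted p from 0.0568 to 0.929).

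In all, limma called 3558 genes higher and 3620 lower in LinPos of 14043 tested, 2096 and 2012 of them by at least 2-fold. The libraries of the groups did not overlap for 44.3% of tested genes, against 2.86% by chance. Set A gave 3357 higher and 3396 lower, and set B 3199 and 3221. Of 18 called genes from the fixed set and the largest differences, 18 were called in the same direction in set A and 18 in set B. Of 23 lists camera called 15, 15 of them also in both sets. With an estimated correlation 2 held, the mesenchymal progenitor markers and growth factor genes.

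The comparison of LinNegSca1Pos with LinNegSca1Neg asked what the Sca1 gate separated within the lineage-negative cells. Ly6a was at 1765 ± 264 against 51.7 ± 12.3 FPKM, a log2 difference of 5.09 ± 0.24 (SE, limma adjusted p = 2.1e-11). Pdgfra, at 101 ± 15.8 against 7.20 ± 0.505 FPKM (log2 difference 3.62 ± 0.20, limma adjusted p = 1.2e-10), and Hic1, at 18.8 ± 6.22 against 1.27 ± 0.193 FPKM (log2 difference 3.08 ± 0.21, adjusted p = 2.0e-09), were higher in LinNegSca1Pos. Pax7 was lower, at 0.0709 ± 0.0382 against 18.2 ± 12 FPKM (log2 difference -3.96 ± 0.43, limma adjusted p = 5.5e-07). Ptprc, at 0.423 ± 0.472 against 3.61 ± 1.18 FPKM (limma adjusted p = 2.1e-04), and Pecam1, at 3.75 ± 2.81 against 9.93 ± 4.25 FPKM (adjusted p = 0.0066), were lower, too. Pecam1 was not called without LinNegSca1Pos replicate 2 (limma adjusted p = 0.0649) or in set A (0.0733). Of 3 gate genes 2 were lower and 1 higher (median log2 difference -1.30, mean 0.69, camera adjusted p = 0.852 towards higher relative to other genes).

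Genes of mesenchymal progenitors, matrix, complement and chemokines were higher in LinNegSca1Pos. The largest increases without overlap were Clec3b at 2002 ± 464 against 11.3 ± 2.89 FPKM (log2 difference 7.35, limma adjusted p = 2.5e-10), Pi16 at 1514 ± 399 against 9.22 ± 1.72 FPKM (log2 difference 7.20, adjusted p = 9.0e-12) and Ptx3, a secreted pattern recognition protein, at 177 ± 70.5 against 1.61 ± 0.913 FPKM (log2 difference 6.06, adjusted p = 1.8e-11). Next were Cd248, endosialin, at 465 ± 99.2 against 7.34 ± 2.44 FPKM (log2 difference 5.83, limma adjusted p = 1.1e-12), Has1, a hyaluronan synthase, at 110.3 ± 22.5 against 1.21 ± 0.290 FPKM (log2 difference 5.65, adjusted p = 4.6e-13) and Emilin2 at 147 ± 12.3 against 2.48 ± 0.152 FPKM (log2 difference 5.40, adjusted p = 7.6e-13). All 12 mesenchymal progenitor markers were higher (median log2 difference 3.39, camera adjusted p = 9.4e-11, adjusted p = 0.0183 with an estimated correlation). Gsn, gelsolin, was at 15085 ± 2723 against 378 ± 36.7 FPKM. Of 16 fibrillar collagen and interstitial matrix genes 10 were higher (median log2 difference 2.14, camera adjusted p = 7.4e-07, adjusted p = 0.132 with an estimated correlation). Fbn1, fibrillin, was at 361 ± 79.2 against 29.7 ± 6.32 and Col3a1 at 4863 ± 1775 against 465 ± 141 FPKM. Of 13 basement membrane genes 11 were higher and 1 lower (median log2 difference 1.38, camera adjusted p = 5.8e-04, adjusted p = 0.229 with an estimated correlation). Nid1 was at 303 ± 54.1 against 69.6 ± 7.22 and Hspg2 at 88.1 ± 17.4 against 22.4 ± 6.45 FPKM. Lama5 at 0.452 ± 0.472 against 9.15 ± 2.57 FPKM was lower. Of 11 complement genes 8 were higher (median log2 difference 1.81, camera adjusted p = 9.2e-06, adjusted p = 0.0593 with an estimated correlation). C4b was at 114 ± 48.1 against 1.75 ± 0.901 and C3 at 1029 ± 159.5 against 24.1 ± 3.24 FPKM. Of 18 chemokine genes 10 were higher and 3 lower (median log2 difference 1.33, camera adjusted p = 0.00219, adjusted p = 0.106 with an estimated correlation). Ccl7 was at 165 ± 54.4 against 6.56 ± 4.78 and Ccl8, a monocyte chemokine, at 46.5 ± 16.1 against 1.56 ± 0.803 FPKM. Ccl3 at 1.22 ± 2.03 against 7.03 ± 3.83, Ccl4 at 1.35 ± 2.34 against 3.75 ± 1.70 and Ccl6 at 2.61 ± 3.01 against 5.76 ± 3.35 FPKM were lower. Ccl3 was not called without LinNegSca1Pos replicate 2 (limma adjusted p = 0.0529), without LinNegSca1Pos replicate 3 (0.0614) or in set A (0.0519). Ccl4 was not called without LinNegSca1Neg replicates 2 or 4 or LinNegSca1Pos replicates 2 or 3, in set A, with a term for set B or after quantile normalization (limma adjusted p from 0.06 to 0.168). Ccl6 was not called without LinNegSca1Neg replicates 2 or 4 or LinNegSca1Pos replicates 2 or 3, in set A, in set B or after quantile normalization (limma adjusted p from 0.0535 to 0.227). Of 18 growth factor genes 8 were higher and 4 lower, or 9 and 4 adjusted over the list alone (median log2 difference 0.59, camera adjusted p = 0.00216, adjusted p = 0.0497 with an estimated correlation). Gdf10 was at 136 ± 43.6 against 7.51 ± 3.66 and Bmp7 at 9.30 ± 0.224 against 0.372 ± 0.106 FPKM. Bmp6 at 6.18 ± 1.98 against 14.8 ± 6.17, Igf2 at 10.8 ± 5.06 against 20.4 ± 8.65, Pdgfb at 0.966 ± 0.765 against 3.40 ± 0.445 and Pdgfa at 3.34 ± 1.06 against 38.3 ± 13.2 FPKM were lower. Bmp6 was not called without LinNegSca1Neg replicates 1 or 2 or LinNegSca1Pos replicates 2 or 3 or in set B (limma adjusted p from 0.0527 to 0.154). Igf2 was not called without LinNegSca1Neg replicates 1 or 2 or LinNegSca1Pos replicate 2 or in set B (limma adjusted p from 0.0861 to 0.359). Of 7 adipocyte genes 4 were higher (median log2 difference 0.61, camera adjusted p = 0.0473, adjusted p = 0.229 with an estimated correlation). Adipoq, adiponectin, was at 5.49 ± 4.10 against 0.279 ± 0.205 and Lpl, lipoprotein lipase, at 253 ± 73.3 against 88.4 ± 17.3 FPKM. These adipocyte genes were not called as a list without LinNegSca1Neg replicates 1 or 2 or LinNegSca1Pos replicate 1, in set A, in set B, with a term for set B or after median-of-ratios scaling (camera adjusted p from 0.0511 to 0.165).

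Genes of satellite cells, mural cells, tenocytes and Schwann cells, of muscle fibres and of the Notch pathway were lower in LinNegSca1Pos. Among the largest decreases were Chodl at 1.28 ± 0.834 against 351 ± 65.1 FPKM (log2 difference -7.31, limma adjusted p = 1.0e-13), Gatm, an enzyme of creatine synthesis, at 4.38 ± 6.83 against 444 ± 32.8 FPKM (log2 difference -7.20, adjusted p = 4.0e-09) and Myl1, a fast myosin light chain, at 25 ± 24.0 against 4413 ± 4037 FPKM (log2 difference -7.16, adjusted p = 1.6e-06). Others were Myh11, smooth muscle myosin, at 5.24 ± 6.50 against 390.1 ± 70.2 FPKM (log2 difference -6.46, limma adjusted p = 7.6e-09) and Pln, a regulator of the calcium pump, at 0.837 ± 1.3 against 116 ± 33.1 FPKM (log2 difference -6.17, adjusted p = 5.9e-09). Of 12 satellite cell markers 11 were lower (median log2 difference -4.00, camera adjusted p = 3.0e-09, adjusted p = 0.0561 with an estimated correlation). Chrdl2 was at 0.181 ± 0.151 against 66.4 ± 29.6 and Myf5, a myogenic factor, at 0.186 ± 0.113 against 54.6 ± 9.20 FPKM. Of 9 Schwann cell markers 8 were lower (median log2 difference -4.36, camera adjusted p = 2.0e-05, adjusted p = 0.106 with an estimated correlation). Kcna1 was at 0.622 ± 0.895 against 58.1 ± 10.5 FPKM. Of 12 pericyte and smooth muscle markers 10 were lower (median log2 difference -3.99, camera adjusted p = 3.7e-05, adjusted p = 0.106 with an estimated correlation). Acta2 was at 39.97 ± 26.7 against 1589 ± 276 and Rgs5, a pericyte marker, at 2.20 ± 1.73 against 109.8 ± 56.6 FPKM. All 10 tenocyte markers were lower (median log2 difference -3.49, camera adjusted p = 3.7e-05, adjusted p = 0.174 with an estimated correlation). Kera, keratocan, was at 10.1 ± 9.61 against 439.8 ± 272 and Tnmd at 25.3 ± 15.6 against 609 ± 158 FPKM. Of 13 Notch pathway genes 9 were lower (median log2 difference -1.79, camera adjusted p = 2.5e-04, adjusted p = 0.0497 with an estimated correlation). Nrarp, a Notch target, was at 0.650 ± 0.670 against 24.1 ± 4.82 and Hey2 at 0.543 ± 0.429 against 21.7 ± 5.28 FPKM. All 11 myofibre and myocyte genes were lower (median log2 difference -5.50, camera adjusted p = 9.2e-06, adjusted p = 0.186 with an estimated correlation). Acta1 was at 28.2 ± 25 against 2558 ± 2347 and Tnnt3 at 35.2 ± 22.2 against 3141 ± 2629 FPKM. In LinNegSca1Neg the myofibre share of the summed FPKM was 1.16% and 0.743% in replicates 1 and 2 and 3.93% and 4.96% in replicates 3 and 4.

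The remaining lists held blood and endothelial cell markers and cell state genes. Of 12 blood endothelial markers 6 were lower and 1 higher (median log2 difference -1.02, camera adjusted p = 0.309). Esam was at 3.93 ± 3.62 against 25.1 ± 15.6 and Fabp4 at 122 ± 97.4 against 482 ± 170.0 FPKM. Tek, the angiopoietin receptor, at 43.7 ± 7.50 against 6.99 ± 1.11 FPKM was higher. Of 5 lymphatic endothelial markers 3 were lower (median log2 difference -0.42, camera adjusted p = 0.0568). Reln was at 0.289 ± 0.391 against 31.4 ± 10.01 FPKM. These lymphatic endothelial markers were called as a list without LinNegSca1Neg replicate 1 (camera adjusted p = 0.0411), without LinNegSca1Pos replicate 1 (0.0369) or after median-of-ratios scaling (0.0466). Of 11 lymphocyte markers 6 were lower (median log2 difference -0.87, camera adjusted p = 0.0647). Cd79b, a part of the B cell receptor, was at 0.216 ± 0.225 against 6.93 ± 1.53 FPKM. These lymphocyte markers were called as a list in set A (camera adjusted p = 0.00745) or after median-of-ratios scaling (0.0471). Of 8 neutrophil markers 3 were lower (median log2 difference -1.62, camera adjusted p = 0.309). S100a8 was at 11.4 ± 12.5 against 166 ± 64.5 FPKM. S100a8 was not called without LinNegSca1Pos replicate 2 (limma adjusted p = 0.0645) or in set B (0.0673). Of 12 macrophage and monocyte markers 3 were higher and 3 lower (median log2 difference 0.13, mean -0.14, camera adjusted p = 0.773). Lyz2 was at 17.6 ± 21.5 against 55.5 ± 31.8 FPKM. Lyz2 was not called without LinNegSca1Pos replicate 2 (limma adjusted p = 0.112) or in set B (0.15). Of 17 immediate early and stress genes 3 were higher and 3 lower (median log2 difference -0.27, camera adjusted p = 0.882). Egr2 was at 11.2 ± 1.47 against 58.2 ± 5.48 and Btg2 at 101 ± 26.1 against 323 ± 73.0 FPKM. By limma 0 of 12 cell cycle genes passed the test, and 0 had an unadjusted p under 0.05 (median log2 difference -0.15, camera adjusted p = 0.921 towards higher relative to other genes). Mki67 was at 3.02 ± 1.93 against 4.997 ± 1.59 FPKM (limma adjusted p = 0.18). Mki67 was called in set A (limma adjusted p = 0.0312). After quantile normalization the median of the cell cycle genes changed sign, to 0.14. By limma 0 of 7 MHC class II genes passed the test, and 0 had an unadjusted p under 0.05 (median log2 difference 0.01, mean -0.26, camera adjusted p = 0.882). H2-Aa was at 10.5 ± 13.3 against 12.8 ± 6.64 FPKM (limma adjusted p = 0.261). H2-Aa was called without LinNegSca1Pos replicate 1 (limma adjusted p = 0.00848). By limma 0 of 4 erythroid genes passed the test, and 0 had an unadjusted p under 0.05 (median log2 difference -0.91, camera adjusted p = 0.845). Beta-s was at 552 ± 462 against 2321 ± 2824 FPKM (limma adjusted p = 0.355). Beta-s was called in set B (limma adjusted p = 0.00892).

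Limma called 3146 genes higher and 4514 lower in LinNegSca1Pos, 1804 and 2136 of them by at least 2-fold. No overlap was seen for 54.7% of tested genes, against 5.71% by chance. Set A gave 3210 higher and 5119 lower, and set B 3724 and 4547. Of 18 checked genes, set A called 17 likewise and set B 18. The median log2 difference of all tested genes was -0.16, and -0.01 after quantile normalization. Of 23 lists camera called 13, 12 of them also in both sets. With an estimated correlation 3 held, the mesenchymal progenitor markers, growth factor genes and Notch pathway genes.

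**Figure D4:**
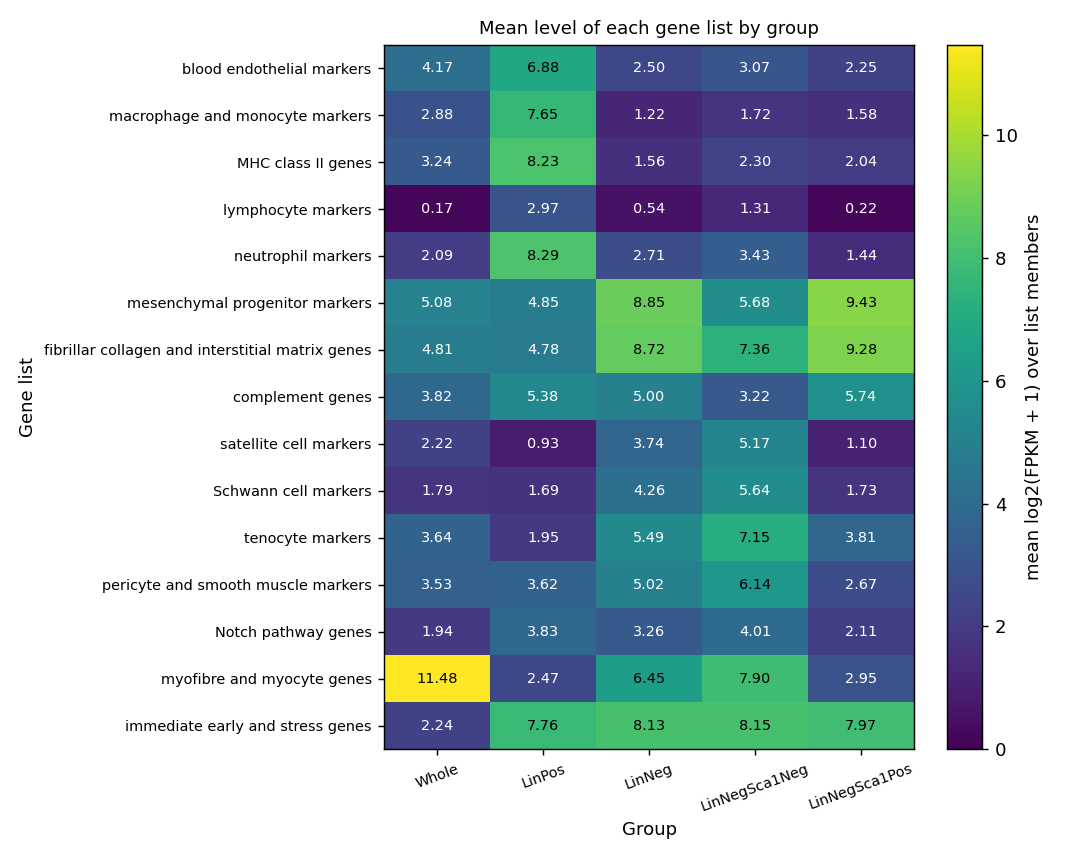
Mean log2(FPKM + 1) over the members of 15 gene lists (y axis) in the 5 groups (x axis), averaged over the libraries of a group. Colour and the printed number give the same value. Mesenchymal progenitor markers are at 9.43 in LinNegSca1Pos and 5.68 in LinNegSca1Neg, and immediate early and stress genes at 2.24 in Whole and between 7.76 and 8.15 in the sorted groups.

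LinPos was next set against Whole. Ptprc was at 131 ± 40.3 against 1.36 ± 0.281 FPKM (log2 difference 5.77 ± 0.30, limma adjusted p = 6.1e-12), Pecam1 at 303 ± 96.0 against 32.8 ± 1.23 FPKM (log2 difference 3.10 ± 0.34, adjusted p = 1.9e-07) and Ly6a at 604 ± 139 against 83.9 ± 13.1 FPKM (log2 difference 2.81 ± 0.23, adjusted p = 2.6e-09), all higher in LinPos. Pdgfra was at 4.88 ± 1.41 against 6.84 ± 0.901 FPKM (log2 difference -0.44, limma adjusted p = 0.0397), Hic1 at 1.52 ± 0.368 against 1.05 ± 0.350 FPKM (adjusted p = 0.184) and Pax7 at 0.185 ± 0.174 against 0.677 ± 0.169 FPKM (adjusted p = 0.268). Pdgfra was not called without LinPos replicates 3 or 4 or Whole replicates 1, 3 or 4, in set A or with a term for set B (limma adjusted p from 0.0532 to 0.258). Pax7 was called in set B (limma adjusted p = 9.4e-04). All 3 gate genes were higher (median log2 difference 3.10, camera adjusted p = 0.0506). The gate list was called without LinPos replicate 3 or Whole replicates 1, 2 or 3, after median-of-ratios scaling or after quantile normalization (camera adjusted p from 0.0216 to 0.0493). The genes with the largest increases were Il1b, interleukin 1 beta, at 486 ± 304 against 0.163 ± 0.126 FPKM (log2 difference 8.36, limma adjusted p = 8.2e-10), S100a8 at 12493 ± 17279.6 against 41.5 ± 39.4 FPKM (log2 difference 8.36, adjusted p = 5.6e-06) and Hspa1b, a heat shock protein, at 708 ± 460.0 against 0.949 ± 0.748 FPKM (log2 difference 8.36, adjusted p = 4.5e-12). Those with the largest decreases were Myh1, a fast myosin heavy chain, at 0.158 ± 0.113 against 2725 ± 620.2 FPKM (log2 difference -11.18, limma adjusted p = 6.2e-13), Atp2a1, the calcium pump of fast fibres, at 3.91 ± 1.87 against 7686 ± 364 FPKM (log2 difference -10.68, adjusted p = 4.8e-12) and Mb, myoglobin, at 2.55 ± 1.54 against 4739 ± 955 FPKM (log2 difference -10.46, adjusted p = 9.1e-13).

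All 17 immediate early and stress genes were higher (median log2 difference 5.19, camera adjusted p = 9.9e-08, adjusted p = 0.00615 with an estimated correlation). Hspa1a was at 577 ± 344 against 1.25 ± 1.12 FPKM. Of 11 myofibre and myocyte genes 10 were lower, or 11 adjusted over the list alone (median log2 difference -9.79, camera adjusted p = 1.3e-08, adjusted p = 0.208 with an estimated correlation). Higher in LinPos were 12 of 12 blood endothelial markers, 12 of 12 macrophage and monocyte markers, 11 of 11 lymphocyte markers, 8 of 8 neutrophil markers, 7 of 7 MHC class II genes, 15 of 18 chemokine genes, 11 of 12 cell cycle genes and 11 of 13 Notch pathway genes. Their median log2 differences ran from 2.31 to 6.74, with camera adjusted p from 1.5e-04 to 0.0185, or adjusted p from 0.208 to 0.536 with an estimated correlation. Emcn was at 189 ± 85.2 against 14 ± 2.05, Ctss at 639 ± 205 against 9.63 ± 1.11, Cd2 at 25.1 ± 12.4 against 0.417 ± 0.351, S100a9 at 6714 ± 7664 against 38.0 ± 33.4, H2-Ab1 at 1972 ± 1385 against 18.2 ± 3.25, Cxcl2 at 298 ± 139.6 against 0.0345 ± 0.0669, Birc5 at 17.4 ± 14.4 against 0.614 ± 0.194 and Hey1 at 32.4 ± 11.5 against 1.79 ± 0.225 FPKM. Against their lists, Ccl11 at 14.9 ± 5.60 against 29.4 ± 3.38, Cxcl14 at 11 ± 3.16 against 29.0 ± 6.67 and Heyl at 2.14 ± 0.618 against 3.70 ± 0.543 FPKM were lower. Heyl was not called without LinPos replicates 3 or 4 or Whole replicates 2 or 3, in set A or with a term for set B (limma adjusted p from 0.0546 to 0.0757). Neutrophil markers were not called as a list with a term for set B (camera adjusted p = 0.0538). Cell cycle genes were not called as a list in set A (camera adjusted p = 0.0718) or with a term for set B (0.0716). Lower in LinPos were 8 of 10 tenocyte markers, 7 of 12 satellite cell markers and 5 of 7 adipocyte genes. The median log2 differences ran from -1.79 to -0.57, with camera adjusted p from 0.00234 to 0.0167, or adjusted p from 0.321 to 0.356 with an estimated correlation. Fmod, fibromodulin, was at 14.7 ± 5.79 against 102 ± 23.5, Asb5 at 0.464 ± 0.220 against 143 ± 26.9 and Cfd, adipsin, at 0.658 ± 0.371 against 26.3 ± 8.52 FPKM. Against their lists, Sdc4, syndecan 4, at 21.1 ± 1.82 against 7.57 ± 0.468 and Pparg at 28.0 ± 6.49 against 2.87 ± 0.948 FPKM were higher. Adipocyte genes were not called as a list in set B (camera adjusted p = 0.0556) or after quantile normalization (0.0501).

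By limma 6855 genes were higher and 3222 lower in LinPos than in Whole, 4803 and 2131 of them by at least 2-fold. No overlap was seen for 69.0% of tested genes, against 2.86% by chance. Of the calls 68.0% were higher, against 52.2% after median-of-ratios scaling and 52.3% after quantile normalization. The median log2 difference of all tested genes was 0.45, 0.05 and 0.04 with these. Set A gave 7288 higher and 3131 lower, and set B 6682 and 3554. Of 10 checked genes, set A called 9 likewise and set B 10. Of 23 lists camera called 13, 11 of them also in both sets. With an estimated correlation 1 held, the immediate early and stress genes.

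LinNeg was compared with Whole in the same way. Ly6a was at 1243 ± 199 against 83.9 ± 13.1 FPKM (log2 difference 3.87 ± 0.23, limma adjusted p = 5.4e-11) and Pdgfra at 105 ± 23.7 against 6.84 ± 0.901 FPKM (log2 difference 3.74 ± 0.19, adjusted p = 6.9e-12), both higher in LinNeg. Hic1, at 5.59 ± 1.39 against 1.05 ± 0.350 FPKM (limma adjusted p = 6.3e-07), and Pax7, at 7.13 ± 5.17 against 0.677 ± 0.169 FPKM (adjusted p = 2.0e-04), were higher, too. Pecam1 was lower, at 5.24 ± 1.39 against 32.8 ± 1.23 FPKM (log2 difference -2.46 ± 0.34, limma adjusted p = 4.4e-06), and Ptprc was at 1.38 ± 1.19 against 1.36 ± 0.281 FPKM (adjusted p = 0.794). Of 3 gate genes 1 was higher and 1 lower (median log2 difference -0.09, mean 0.44, camera adjusted p = 0.84). The largest increases were those of Fos, an immediate early factor, at 1525 ± 394 against 2.50 ± 0.535 FPKM (log2 difference 8.74, limma adjusted p = 1.9e-15), Hspa1b at 569 ± 266 against 0.949 ± 0.748 FPKM (log2 difference 8.14, adjusted p = 1.0e-11) and Cxcl1 at 378 ± 51.8 against 0.418 ± 0.308 FPKM (log2 difference 8.08, adjusted p = 2.9e-14). The largest decreases were those of Myh1 at 5.92 ± 3.97 against 2725 ± 620.2 FPKM (log2 difference -8.75, limma adjusted p = 2.6e-11), Ckmt2, mitochondrial creatine kinase, at 5.39 ± 2.71 against 1718 ± 60.8 FPKM (log2 difference -8.15, adjusted p = 1.5e-13) and Myh2, a fast myosin heavy chain, at 3.51 ± 3.21 against 635 ± 146 FPKM (log2 difference -7.35, adjusted p = 4.0e-11).

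All 17 immediate early and stress genes were higher (median log2 difference 5.53, camera adjusted p = 3.6e-09, adjusted p = 0.00228 with an estimated correlation). Fosb was at 320.2 ± 79.4 against 0.190 ± 0.151 FPKM. Higher in LinNeg were 12 of 12 mesenchymal progenitor markers, 16 of 16 fibrillar collagen and interstitial matrix genes, 13 of 13 basement membrane genes, 8 of 9 Schwann cell markers, 15 of 18 growth factor genes and 10 of 18 chemokine genes, or 12, 16, 13, 8, 15 and 11 adjusted over the list alone. Their median log2 differences ran from 1.52 to 3.88, with camera adjusted p from 2.7e-06 to 0.0366, or adjusted p from 0.0578 to 0.332 with an estimated correlation. Pi16 was at 549 ± 152 against 16.8 ± 2.42, Col3a1 at 3429 ± 825 against 116 ± 38.0, Nid1 at 399 ± 61.1 against 25.1 ± 1.85, Kcna1 at 19.1 ± 1.69 against 0.611 ± 0.028, Il6, interleukin 6, at 106 ± 24.6 against 0.187 ± 0.0613 and Ccl7 at 107 ± 19.9 against 0.703 ± 0.386 FPKM. Against their lists, Pdgfb at 1.67 ± 0.178 against 6.72 ± 0.25, Vegfa at 45.0 ± 5.28 against 75.9 ± 17.2, Ccl6 at 1.68 ± 0.185 against 9.31 ± 2.97 and Ccl9 at 0.673 ± 0.194 against 3.09 ± 1.07 FPKM were lower. Chemokine genes were not called as a list with a term for set B (camera adjusted p = 0.0823). Lower in LinNeg were 10 of 11 myofibre and myocyte genes, 10 of 12 blood endothelial markers, 9 of 12 macrophage and monocyte markers, 6 of 7 MHC class II genes and 4 of 7 adipocyte genes. The median log2 differences ran from -5.35 to -1.72, with camera adjusted p from 2.7e-06 to 0.0133, or adjusted p from 0.27 to 0.331 with an estimated correlation. Ttn, titin, was at 0.284 ± 0.131 against 163 ± 10.01, Egfl7 at 2.50 ± 0.858 against 22.3 ± 5.39, C1qb at 0.466 ± 0.235 against 16.8 ± 6.28, H2-Aa at 4.88 ± 3.58 against 36.8 ± 10.4 and Cfd at 0.417 ± 0.392 against 26.3 ± 8.52 FPKM. Against their lists, Myog, a factor of muscle differentiation, at 9.80 ± 5.92 against 1.29 ± 0.456, Tek at 48.6 ± 9.49 against 8.96 ± 1.05 and Pparg at 5.53 ± 0.514 against 2.87 ± 0.948 FPKM were higher. Pparg was not called after median-of-ratios scaling (limma adjusted p = 0.24) or after quantile normalization (0.264).

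Here limma called 6676 genes higher and 3062 lower in LinNeg, 4107 and 1946 of them by at least 2-fold. No overlap was seen for 67.6% of tested genes, against 2.86% by chance. Of the calls 68.6% were higher, against 48.5% after median-of-ratios scaling and 52.0% after quantile normalization. The median log2 difference of all tested genes was 0.43, -0.001 and 0.05 with these. Set A gave 7138 higher and 3063 lower, and set B 6358 and 3345. Of 11 checked genes, each set called 11 likewise. After median-of-ratios scaling 4878 genes were lower. Of 23 lists camera called 12, 12 of them also in both sets. With an estimated correlation 1 held, the immediate early and stress genes.

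The last comparisons set each Sca1 fraction against LinNeg, from which it was taken. In LinNegSca1Pos, Hic1 was higher, at 18.8 ± 6.22 against 5.59 ± 1.39 FPKM (log2 difference 1.56 ± 0.21, limma adjusted p = 4.3e-05), and Pax7 lower, at 0.0709 ± 0.0382 against 7.13 ± 5.17 FPKM (log2 difference -2.68 ± 0.43, adjusted p = 1.9e-04). Ly6a was at 1765 ± 264 against 1243 ± 199 FPKM (limma adjusted p = 0.12), Pdgfra at 101 ± 15.8 against 105 ± 23.7 (adjusted p = 0.901), Pecam1 at 3.75 ± 2.81 against 5.24 ± 1.39 (adjusted p = 0.275) and Ptprc at 0.423 ± 0.472 against 1.38 ± 1.19 (adjusted p = 0.114). By limma 0 of 3 gate genes passed the test, and 1 had an unadjusted p under 0.05 (median log2 difference -0.55, camera adjusted p = 0.785). The largest increases here were Ccl8 at 46.5 ± 16.1 against 8.38 ± 8.08 FPKM (log2 difference 2.72, limma adjusted p = 0.00718), Ndufs5, a subunit of respiratory complex I, at 79.6 ± 27.9 against 13.3 ± 8.36 FPKM (log2 difference 2.64, adjusted p = 3.7e-04) and Rpph1, the RNA of RNase P, at 16 ± 11.3 against 1.44 ± 0.769 FPKM (log2 difference 2.62, adjusted p = 9.5e-04). Among the largest decreases here were Myl1 at 25 ± 24.0 against 1058 ± 911 FPKM (log2 difference -5.40, limma adjusted p = 1.7e-04) and Gatm at 4.38 ± 6.83 against 126 ± 20.7 FPKM (log2 difference -5.37, adjusted p = 1.5e-06). Ccl8 was not called in set A (limma adjusted p = 0.0514). Lower in LinNegSca1Pos were 10 of 12 satellite cell markers, 7 of 9 Schwann cell markers, 9 of 12 pericyte and smooth muscle markers, 9 of 13 Notch pathway genes, 10 of 11 myofibre and myocyte genes and 6 of 10 tenocyte markers, or 11, 7, 9, 9, 10 and 9 adjusted over the list alone. Their median log2 differences ran from -4.05 to -0.94, with camera adjusted p from 6.1e-12 to 5.9e-04, or adjusted p from 0.0442 to 0.441 with an estimated correlation. Chodl was at 1.28 ± 0.834 against 89.7 ± 7.25, Kcna1 at 0.622 ± 0.895 against 19.1 ± 1.69, Myh11 at 5.24 ± 6.50 against 175 ± 63.7, Nrarp at 0.650 ± 0.670 against 9.92 ± 4.54, Acta1 at 28.2 ± 25 against 1007 ± 1141 and Kera at 10.1 ± 9.61 against 117 ± 92.4 FPKM. Against their lists, Ngfr at 4.10 ± 3.56 against 0.756 ± 0.309 FPKM was higher. Ngfr was not called without LinNeg replicate 3 or LinNegSca1Pos replicates 1 or 3 or in set A or B (limma adjusted p from 0.0563 to 0.174). Of 16 fibrillar collagen and interstitial matrix genes 6 were higher, or 7 adjusted over the list alone (median log2 difference 0.49, camera adjusted p = 0.00867, adjusted p = 0.576 with an estimated correlation). Eln, elastin, was at 302 ± 115 against 104 ± 21.1 FPKM. These fibrillar collagen and interstitial matrix genes were not called as a list without LinNegSca1Pos replicate 2 (camera adjusted p = 0.12), in set B (0.101) or after quantile normalization (0.337). Of 12 mesenchymal progenitor markers 5 were higher (median log2 difference 0.48, camera adjusted p = 0.0616). Clec3b was at 2002 ± 464 against 430.3 ± 209.8 FPKM. These mesenchymal progenitor markers were called as a list without LinNegSca1Pos replicate 2 (camera adjusted p = 0.0222).

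Between LinNegSca1Pos and LinNeg limma called 2233 genes higher and 2407 lower, 944 and 782 of them by at least 2-fold. No overlap was seen for 38.7% of tested genes, against 5.71% by chance. Set A gave 2306 higher and 2870 lower, and set B 3080 and 2719. Of 8 checked genes, set A called 7 likewise and set B 8. Without LinNegSca1Pos replicate 3 the lower genes numbered 1582. Of 23 lists camera called 7, 6 of them also in both sets. With an estimated correlation 2 held, the Notch pathway genes and satellite cell markers.

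In LinNegSca1Neg, Ly6a was at 51.7 ± 12.3 against 1243 ± 199 FPKM (log2 difference -4.58 ± 0.23, limma adjusted p = 7.5e-11), Pdgfra at 7.20 ± 0.505 against 105 ± 23.7 FPKM (log2 difference -3.67 ± 0.19, adjusted p = 8.5e-11) and Hic1 at 1.27 ± 0.193 against 5.59 ± 1.39 FPKM (adjusted p = 1.7e-05), all lower than in LinNeg. Pax7 was higher, at 18.2 ± 12 against 7.13 ± 5.17 FPKM (limma adjusted p = 0.0244), and so was Ptprc, at 3.61 ± 1.18 against 1.38 ± 1.19 FPKM (adjusted p = 0.0148). Pecam1 was at 9.93 ± 4.25 against 5.24 ± 1.39 FPKM (limma adjusted p = 0.121). Pax7 was not called without LinNeg replicates 3 or 4 or LinNegSca1Neg replicates 1 or 2 (limma adjusted p from 0.0642 to 0.0912). Ptprc was not called without LinNeg replicates 2 or 4, in set B or with the replicate number as a block in a fit of these groups alone (limma adjusted p from 0.0521 to 0.248). Pecam1 was called with the replicate number as a block in a fit of these groups alone (limma adjusted p = 0.0396). Of 3 gate genes 1 was higher and 1 lower, or 2 and 1 adjusted over the list alone (median log2 difference 0.75, mean -0.93, camera adjusted p = 0.362 towards lower relative to other genes). The largest decreases against LinNeg were Pi16 at 9.22 ± 1.72 against 549 ± 152 FPKM (log2 difference -5.71, limma adjusted p = 1.2e-10), Krtdap at 0.345 ± 0.156 against 61.1 ± 15 FPKM (log2 difference -5.50, adjusted p = 4.8e-11) and Ptx3 at 1.61 ± 0.913 against 94.5 ± 8.29 FPKM (log2 difference -5.25, adjusted p = 8.5e-11). The largest increases against LinNeg were Snora41, a small nucleolar RNA, at 26.8 ± 5.01 FPKM against 18.1 in LinNeg replicate 2 and the floor of 0.001 in the other 3 libraries (log2 difference 3.72, limma adjusted p = 0.0194), Myog at 43.7 ± 26.7 against 9.80 ± 5.92 FPKM (log2 difference 2.07, adjusted p = 5.9e-04) and Myoz2, a sarcomere protein, at 47.0 ± 36.6 against 9.64 ± 4.54 FPKM (log2 difference 2.05, adjusted p = 0.00289). Snora41 was not called without LinNeg replicates 1, 3 or 4 or in set A (limma adjusted p from 0.0552 to 0.288).

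Lower in LinNegSca1Neg were 12 of 12 mesenchymal progenitor markers, 10 of 16 fibrillar collagen and interstitial matrix genes, 7 of 11 complement genes, 10 of 18 growth factor genes, 9 of 18 chemokine genes, 9 of 13 basement membrane genes and 1 of 7 adipocyte genes, or 12, 11, 7, 12, 10 (with 4 opposite), 9 and 1 adjusted over the list alone. The median log2 differences ran from -3.25 to -0.13, with camera adjusted p from 6.6e-22 to 0.042, or adjusted p from 5.4e-04 to 0.234 with an estimated correlation. Clec3b was at 11.3 ± 2.89 against 430.3 ± 209.8, Fbn1 at 29.7 ± 6.32 against 323 ± 122, C3 at 24.1 ± 3.24 against 845 ± 162, Gdf10 at 7.51 ± 3.66 against 127 ± 28.4, Cxcl13 at 1.3 ± 0.636 against 50.05 ± 12.9, Nid1 at 69.6 ± 7.22 against 399 ± 61.1 and Lpl at 88.4 ± 17.3 against 269 ± 49.6 FPKM. Against their lists, Igf2 at 20.4 ± 8.65 against 9.80 ± 2.44, Pdgfa at 38.3 ± 13.2 against 17.6 ± 7.49, Pdgfb at 3.40 ± 0.445 against 1.67 ± 0.178, Ccl6 at 5.76 ± 3.35 against 1.68 ± 0.185, Col18a1 at 33.3 ± 3.13 against 22.6 ± 2.47 and Lama5 at 9.15 ± 2.57 against 4.27 ± 0.856 FPKM were higher. Igf2 was not called without LinNeg replicates 1 or 3 or LinNegSca1Neg replicates 1 or 2, in set B or after median-of-ratios scaling (limma adjusted p from 0.0502 to 0.315). Pdgfa was not called without LinNeg replicate 1 (limma adjusted p = 0.05002). Pdgfb was not called without LinNeg replicates 1, 3 or 4 or LinNegSca1Neg replicates 3 or 4, in set A, in set B, after median-of-ratios scaling or after quantile normalization (limma adjusted p from 0.0565 to 0.128). Ccl6 was not called without LinNeg replicate 1 or LinNegSca1Neg replicates 2 or 4 or in set A or B (limma adjusted p from 0.0544 to 0.225). Col18a1 was not called without LinNeg replicates 2 or 3 or LinNegSca1Neg replicate 3, in set A, in set B, after median-of-ratios scaling or after quantile normalization (limma adjusted p from 0.0505 to 0.158). Adipocyte genes were not called as a list without LinNeg replicates 2 or 4 or LinNegSca1Neg replicates 1 or 2, in set B, with a term for set B, after median-of-ratios scaling or after quantile normalization (camera adjusted p from 0.0516 to 0.184). Higher in LinNegSca1Neg were 10 of 12 satellite cell markers, 7 of 9 Schwann cell markers, 9 of 10 tenocyte markers, 9 of 12 pericyte and smooth muscle markers, 7 of 13 Notch pathway genes and 5 of 11 myofibre and myocyte genes, or 12, 8, 10, 11, 9 and 8 adjusted over the list alone. Their median log2 differences ran from 0.93 to 1.73, with camera adjusted p from 5.1e-08 to 0.0104, or adjusted p from 0.0637 to 0.465 with an estimated correlation. Chodl was at 351 ± 65.1 against 89.7 ± 7.25, Mbp, myelin basic protein, at 347 ± 27.2 against 112 ± 15.3, Kera at 439.8 ± 272 against 117 ± 92.4, Higd1b at 17.2 ± 11.9 against 4.56 ± 1.77, Hey1 at 20.9 ± 3.96 against 7.61 ± 2.15 and Mb at 256.3 ± 117 against 72.1 ± 45.6 FPKM. Against their lists, Rbpj, the DNA-binding partner of Notch, at 22.2 ± 2.29 against 34.2 ± 4.29 FPKM was lower. Mbp was not called in set A (limma adjusted p = 0.152) or in set B (0.136). Higd1b was not called without LinNeg replicate 4 (limma adjusted p = 0.0503), without LinNegSca1Neg replicate 2 (0.0545) or in set B (0.109). Mb was not called in set B (limma adjusted p = 0.0557). Of 5 lymphatic endothelial markers 2 were higher, or 3 adjusted over the list alone (median log2 difference 0.59, camera adjusted p = 0.0584). These lymphatic endothelial markers were called as a list without LinNeg replicate 1 or LinNegSca1Neg replicate 2, in set B, after median-of-ratios scaling or with the replicate number as a block (camera adjusted p from 0.038 to 0.0499).

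In LinNegSca1Neg against LinNeg limma called 2324 genes higher and 1308 lower, 672 and 715 of them by at least 2-fold. No overlap was seen for 24.8% of tested genes, against 2.86% by chance. Of the calls 64.0% were higher, against 50.8% after median-of-ratios scaling and 50.5% after quantile normalization. The median log2 difference of all tested genes was 0.17, 0.07 and 0.06 with these. Set A gave 2133 higher and 1294 lower, and set B 1383 and 963. Of 11 checked genes, each set called 10 likewise. With the replicate number as a block in a fit of these groups alone the counts were 4354 and 1926, and with a term for set B 3558 and 1692. Of 23 lists camera called 13, 12 of them also in both sets. With an estimated correlation 4 held, the mesenchymal progenitor markers, complement genes, growth factor genes and chemokine genes.

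Each parent of the sort was compared with its children. Of 5894 genes at least 2-fold apart between LinNegSca1Pos and LinNegSca1Neg, the LinNeg mean lay between for 5116 (86.8%). By non-negative least squares LinNeg was fitted by 0.475 ± 0.094 of LinNegSca1Pos and 0.439 ± 0.303 of LinNegSca1Neg (mean ± SD over 4 LinNeg libraries). Fitted and measured values had r = 0.98 across genes, which are not independent replicates. Whole, a parent by its title only, did not lie between LinPos and LinNeg in the same way. Of 5571 genes that differed at least 2-fold between those, Whole had a mean between them for 2040, or 36.6%, below both for 47.4% and above both for 16%. The fitted weights were 0.592 ± 0.03 for LinNeg and 0 for LinPos in each Whole library (r = 0.703 across genes). A weight is a share of mRNA only if every fraction yields mRNA alike, which these data do not show.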

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

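The tests of gene copies, of Whole and of fibre fragments were chosen only after their results were seen, while those of length and GC content, fibre and red-cell RNA, differentiating cells and the splits were set before.

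In groups of 4, a library was singled out where its gap to the nearest other exceeded Dixon's 95% critical share of the range, which chance gives for about 1 in 20 groups. Of 325 groups of values 37 passed, 12 of them through LinPos replicate 3. In that library S100a8 stood at 38348 FPKM, Acta2 at 331.5, Cxcl1 at 69.89, Tnnt3 at 46.94, Birc5 at 38.95, Mki67 at 25.18, Cnn1 at 9.194, Hey2 at 4.086, Myh1 at 0.3273 and Plin1 at 0.1212, all above the other LinPos libraries, and Ly6a below them at 396.3. Its myofibre share of 0.039% was above the others (0.017% to 0.02%). LinPos replicate 4 was above the others for Beta-s (14466 FPKM) and C1qc (820.5) and below them for Kcna1 (0.5831). LinNeg replicate 3 was high for S100a8 (709.9), Mb (139.7), Alas2 (19.27), H2-Aa (10.25), Ctss (4.95) and Cd2 (1.441) and low for Igf2 (6.144), replicate 4 was high for Thbs4 (674.5) and Kera (254.8) and replicate 2 for Snora41 (18.08). LinNegSca1Neg replicate 1 was low for Ccl3 (1.319) and high in its share of immediate early and stress genes (2.315%, others 1.793% to 1.841%), and replicate 2 was high for Tmem8c (12.75) and Gm7325 (6.52). In Whole, replicate 1 was low for Ly6a (64.45) and high for Myh8 (113.3), Hspa1b (2.069) and Cxcl2 (0.1348), replicate 2 low for Il6 (0.09507) and high for Gm7325 (0.1348), and replicate 4 high for Col3a1 (172.8) and Ctss (11.29).

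In replicates 3 and 4 of LinPos, LinNeg and LinNegSca1Neg 2332 genes were called higher and 4142 lower than in replicates 1 and 2, of 14043 tested. Among called genes with a symbol listed once, 926 differed by at least 2-fold. Reads shared between genes were argued against as the whole source, since 15.3% of these 926 genes shared at least 20% of their 31-base words with another gene. Of other genes 7.5% did, so that such sharing may account for part. Added RNA of fibres and red cells alone was argued against too, since 505 genes were lower by at least 2-fold. Length or GC content stays open, with rank correlations across genes of -0.18 and -0.13. A separate day or preparation may be the source, but the labels give none, and the design names no biological difference between these sets.

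Immediate early and stress genes were lower in Whole than in every sorted fraction. Dilution by fibre mRNA was argued against, because Whole held 0.101 of the level that its endothelial and mesenchymal markers predict (0.066 to 0.117 by library). A response of the sorted libraries to dissociation and sorting is a candidate explanation only if Whole did not go through that dissociation, which the labels do not settle, and 17 of 17 genes had every sorted library above every Whole library. Whole also differs from the fractions in cell content, so the biology of the cells themselves stays open and untested.

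Myofibre genes were higher in LinNegSca1Neg than in LinNegSca1Pos. Fibre fragments or free RNA would keep fibre genes in the proportions of Whole, yet over 10 genes the highest ratio to Whole was at least 17.4 times the lowest in each library, which argues against them as the whole source. The longest transcripts had the lowest ratios. A test on 7 genes with transcripts under 3000 bases, made after that was seen, gave 2.0, 2.4, 4.1 and 5.9, leaving fragments open. Differentiating muscle cells could contribute too. Of 9 early differentiation genes 3 had every LinNegSca1Neg library above every Whole library, which fibre RNA as in Whole would not give. Failing genes such as Myh8 were high in Whole, so the extent stays open.

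In all 6 comparisons the real split of the libraries, 1 of 35, called the most genes. That share, the lowest possible, was not adjusted over the 6, so chance stays open. In the paired comparisons only 8 splits part every same-numbered pair, too few for a share under 0.05. For LinPos against LinNeg the real split called 7178 genes and the highest other of these 8 called 1, and for LinNegSca1Neg against LinNeg 3632 and 3. Over all splits the highest others were 2070 and 2576, both the split into sets A and B, which points to the structure of the samples. For LinNegSca1Pos against LinNegSca1Neg the values were 7660 and 5117 and for LinNegSca1Pos against LinNeg 4640 and 2371. For LinPos and LinNeg against Whole they were 10077 and 1, and 9738 and 0.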

How the results depend on the processing

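The set, paired-group and list refits named as added were chosen only after the data were seen, and the others were planned. Across all alternatives 12458 log2 differences of named genes kept their side of the threshold, 361 fell short of it and 166 newly passed it. Called genes kept their direction. A change of sign counted as kept where neither fit called the gene or list. For the lists the numbers were 2047, 84 and 76, with 1 that reversed, the gate list in LinNeg against Whole under fry (adjusted p = 4.32e-04), a test that does not compare the list with other genes. Counts of higher genes stayed within 1.5 times the reported count in 123 fits and counts of lower genes in 124. Beyond that were 4878 lower genes for LinNeg against Whole after median-of-ratios scaling, which moved the median of all genes, and the higher genes for LinNegSca1Neg against LinNeg, 3558 with a term for set B, 1383 in set B alone with fewer libraries and 4354 with the replicate block in a fit of these groups alone. Counts of genes at least 2-fold higher or lower stayed within 1.5 times in 115 and 119 fits. A pseudocount of 5, which shrinks differences of low genes, gave 1266 higher and 1013 lower for LinPos against LinNeg, 1068 and 932 for LinNegSca1Pos against LinNegSca1Neg, 451 and 249 for LinNegSca1Pos against LinNeg, 244 and 429 for LinNegSca1Neg against LinNeg, and 2801 and 2069 higher for LinPos and LinNeg against Whole. A pseudocount of 0.1 gave 1423 lower for LinNegSca1Pos and 1149 higher for LinNegSca1Neg against LinNeg. Median-of-ratios scaling gave 3197 lower for LinPos against Whole, 2593 higher and 3184 lower for LinNeg against Whole, and 433 higher for LinNegSca1Neg against LinNeg. Quantile normalization gave 2727 higher for LinNeg against Whole and set B alone 1569 higher for LinNegSca1Pos against LinNeg. Leaving out single replicates gave 1582 to 2297 lower genes for LinNegSca1Pos against LinNeg, the fewest without LinNegSca1Pos replicate 3, and the cause was not tested. The share of genes with Whole between LinPos and LinNeg was 41.2% with log2-scale means, 48.5% for genes differing at least 4-fold and 35.5% to 37.5% leaving out single replicates. With the replicate number as a block in the fit of all groups 3804 genes were higher and 3861 lower for LinPos against LinNeg and 2682 and 1435 for LinNegSca1Neg against LinNeg. In the fit of these groups alone the blood endothelial markers were also called (camera adjusted p = 0.0405), and the block changed no other call printed for these comparisons than those given there. In the other 4 comparisons same-numbered libraries correlated at -0.35 to 0.18, and 2, 1, 1 and 1 libraries of the first group correlated best with their own number. The block gave 3259 higher and 4824 lower genes for LinNegSca1Pos against LinNegSca1Neg, 7137 and 3376 for LinPos against Whole, 6932 and 3223 for LinNeg against Whole and 2372 and 2675 for LinNegSca1Pos against LinNeg. It also called lymphocyte markers in LinNegSca1Pos against LinNegSca1Neg (camera adjusted p = 0.0438) and tenocyte markers in LinNeg against Whole (0.0425). List medians changed sign after both scalings for Schwann cell markers in LinPos against Whole and erythroid genes in LinNeg against Whole, and after quantile normalization for lymphatic endothelial markers in LinNegSca1Pos against LinNeg. Low values of the shallow LinNegSca1Pos replicate 3 limit what can be seen for weakly expressed genes.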

Other observations

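The list of early muscle differentiation genes was set before its values were seen and after the data had been opened. Tmem8c, a muscle cell fusion gene, was at 6.91 ± 3.92 FPKM in LinNegSca1Neg (SD, n = 4) against 0.083 ± 0.095 in Whole and 0.091 ± 0.156 in LinNegSca1Pos (n = 3). Chrna1, a subunit of the acetylcholine receptor, was at 13.98 ± 4.71 against 4.65 ± 0.555 and 0.104 ± 0.063 FPKM. Gm7325, also needed for fusion, was at 2.20 ± 2.89 against 0.034 ± 0.067 and 0.137 ± 0.157 FPKM. Actc1, cardiac actin, was at 98.2 ± 59.2 against 120.9 ± 30.4 and 1.14 ± 1.27 FPKM, and Myh8, a perinatal myosin, at 0.746 ± 0.28 against 87.6 ± 17.3 and 0.097 ± 0.04. Actc1 and Myh8 were picked after their values were seen, and single genes of this list were not tested.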
